A study of Mus musculus with 12 samples.

How the data were processed

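RNA sequencing libraries were made with the TruSeq RNA Sample Prep Kit v2 from 500 ng of RNA per sample with an integrity number above 9.5, per the labels. RNA was taken from wild-type, Smad2 and Smad3 double-knockout and Smad4 knockout E14Tg2a.IV mouse ES cells before and 4 days after LIF was removed, 2 libraries in each of the 6 groups, per the labels. Samples were grouped by the genotype and time point in their titles, which name every library. Aligner, annotation, strand setting and filters were not given in the sources used here.

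The first table holds the counts that the authors deposited, whole numbers per Ensembl gene ID with no normalization recorded, 1 column per library and none pooled. The second holds FPKM values (fragments per kilobase of transcript, scaled to the library) that the authors deposited, 1 row per gene symbol, with no further scaling stated. Build mm10 and the tools Cufflinks, StringTie and DESeq2 are named, without versions or roles, per the submitters' processing notes. Values of 1 (4966) were rarer in the count table than values of 2 (6989) or 3 (6895), so the counts need not be direct tallies of reads. Of the 32285 gene IDs, 32158 were matched to a symbol through the GENCODE M21 annotation and 127 were not. The FPKM table has 32245 rows, and 31389 symbols occur in both tables. Each of the 12 FPKM columns correlated best with the count column of its own name (lowest r after centring 0.954). Every column of both tables was mapped to a library, and no sample was left out. Within groups, log2 CPM of the replicates correlated at 0.973 to 0.995, and their counts differed by far more than counting noise (chi-square per gene 31.2 to 248 over genes with at least 20 counts), so no library was a copy of another.

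Counts were fitted with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3), with TMM scaling and filterByExpr, which kept 18693 genes. The fit held all 12 libraries and 1 coefficient per group. Adjusted p-values are Benjamini-Hochberg values, and a gene was called at an adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.286. The contrasts were each knockout against WT at each day, day 4 against day 0 in each genotype, the knockouts against each other at each day, and the difference of each genotype effect between the days.

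The 26 gene lists, written from general knowledge, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. They cover Nodal and activin targets, BMP targets, the pathway, naive, shared and primed pluripotency, the germ layers and extraembryonic lineages, 2-cell genes, germ cells, fibroblasts, Wnt, LIF and p53 targets, hypoxia, cell cycle, mesenchyme, Hox, Y-linked, mitochondrial and imprinted genes, and blood and endothelium. Members with an adjusted p below 0.05 were counted over all genes and adjusted over the list alone, and each call was repeated with an estimated correlation and with fry. The tests, the lists, the rule for named genes and the alternatives other than those said to be added were chosen before the data were examined.

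The rule named, for the knockouts against WT and for WT day 4 against day 0, the 6 genes with the largest rise and the 6 with the largest drop. For the other contrasts it named 4 and 4. A gene had to be called, its groups had to be free of overlap in CPM, and its mean had to be at least 5 CPM in the higher group. Gene models without an established name were passed over. Smad2, Smad3 and Smad4 were always reported, and up to 4 members of each described list were named beside them. Chml, Hprt and Mid1 outside the contrasts where the rule named them, Xist, and the genes of the closing section that are not named by the rule were chosen after their values were seen.

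The alternatives set in advance were a minimum absolute log2 fold change of 1, a minimum of 1 CPM in 2 libraries, no filter, RLE size factors, the DESeq2 Wald test (DESeq2 1.42.0), limma 3.58.1 on log2(FPKM + 1) with and without a filter and on log2(FPKM + 0.1), the replicate number as a block, a fit with only the groups of the contrast, and leaving out each library in turn. A group left with 1 library was assumed to vary like the others. Alternatives added after seeing the data were a length and GC correction, a fit without the WT day 0 libraries, leaving out each library for the lists, and leaving out genes on chromosomes 8, X and Y. The correction removed each library's trend with exon length and GC content through offsets from a spline with 5 degrees of freedom. It covered 18682 genes, 99.9% of those tested, and the coefficient of variation under it was 0.235. Chromosome medians use genes with a mean of at least 1 CPM and 1000 bootstrap draws. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 handled tables and figures.

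The tests were tried on simulated counts for S23DKO against WT at day 0, with 100 genes changed 2-fold and 100 changed 4-fold. edgeR recovered 8% of the 2-fold and 60% of the 4-fold genes, and 9.33% of its calls were false. DESeq2 recovered 25% and 73%, with 27.4% false, and limma on log2(CPM + 1) recovered 11% and 64%, with 7.41% false. With the real length and GC trends added, edgeR recovered 7% and 47% with 22.9% false, against 9%, 58% and 2.90% once corrected. Camera called a changed list (adjusted p = 3.39e-22) and 0 of 20 random lists, but random genes do not test the preset correlation.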

Results

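Gene-level RNA-seq counts were available for 12 libraries of mouse embryonic stem cells, in 6 groups of 2 replicates. The cells were E14Tg2a.IV, a line derived from E14Tg2a, which was isolated as an Hprt-deficient line. The libraries labelled S4KO held Hprt transcripts (208 ± 6.11 CPM at day 0 and 170 ± 1.29 CPM at day 4), unlike those of WT and S23DKO. A parental line other than that of WT was therefore not excluded for S4KO. S23DKO nearly lacked several Y-linked transcripts and had more Xist than WT. Differences between the lines thus limit every comparison between genotypes. The 3 genotypes were wild type (WT), a Smad2 and Smad3 double knockout (S23DKO) and a Smad4 knockout (S4KO). Each was taken undifferentiated (day 0) and after 4 days without LIF as embryoid bodies (day 4). Smad2 and Smad3 carry Nodal, activin and TGF-beta signals to the nucleus, and Smad4 is the partner that they share with the BMP-responsive Smads. The comparisons ask how the genotypes differ before and after differentiation. Total counts, replicate 1 then replicate 2, were 49829720 and 51353258 in WT day 0, 53604809 and 51618920 in WT day 4, 50952687 and 46132635 in S23DKO day 0. They were 55806858 and 50123451 in S23DKO day 4, 49523324 and 50166446 in S4KO day 0, 50876757 and 31566376 in S4KO day 4. Mitochondrial transcripts took 6.74% of the counts in S23DKO day 0 replicate 2 and between 1.87% and 3.93% in the other libraries. Ribosomal-protein transcripts took 14.1% and 10.3% of the WT day 0 counts and between 4.84% and 7.44% elsewhere.

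Levels are given as CPM (counts scaled to the library size), mean ± SD, and log2 fold changes ± SE, with n = 2 libraries in each group throughout. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, part of which may be technical. Where a group had no counts for a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% counting interval. Intervals and floors cover counting error only.

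**Figure D1:**
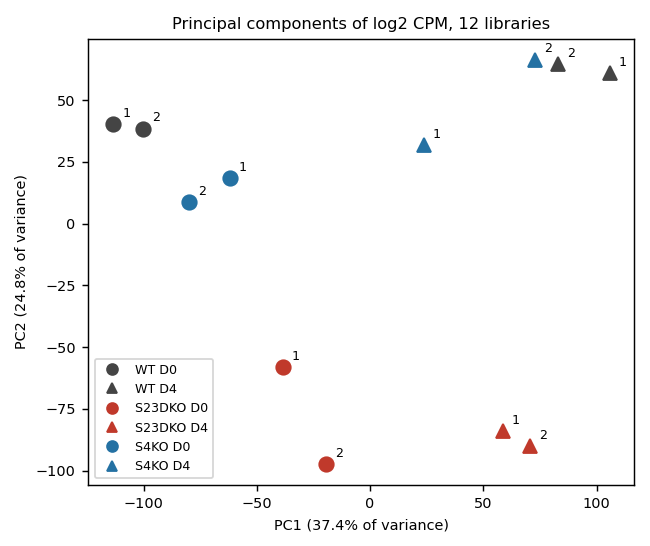
Principal components of the 12 libraries, with 37.4% of the variance on the horizontal axis and 24.8% on the vertical axis; each point is a library. The S23DKO libraries lie below those of the other 2 genotypes, and day 4 lies to the right of day 0 in each genotype.

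The targeted genes were still transcribed in their knockouts. Smad2 (ENSMUSG00000024563, chromosome 18, 76241580 to 76310963, build mm10) had 42.8 ± 7.02 CPM in S23DKO and 34.1 ± 6.61 CPM in WT at day 0, and 47.5 ± 1.10 CPM against 83.0 ± 19.6 CPM at day 4. Smad3 (ENSMUSG00000032402, chromosome 9, 63646767 to 63757994) had 16.4 ± 4.73 CPM in S23DKO and 10.6 ± 1.27 CPM in WT at day 0, and 30.0 ± 1.79 CPM against 49.0 ± 1.81 CPM at day 4. Neither passed in S23DKO, with log2 fold changes of 0.33 ± 0.25 (adjusted p = 0.348) for Smad2 and 0.63 ± 0.26 (0.0831) for Smad3 at day 0. At day 4 they were -0.80 ± 0.25 (0.0528) and -0.70 ± 0.26 (0.0869). Smad4 (ENSMUSG00000024515, chromosome 18, 73639009 to 73703780) was higher in S4KO than in WT at day 0, 90.0 ± 14.7 CPM against 50.9 ± 1.89 CPM (log2 fold change 0.82 ± 0.20, adjusted p = 0.0187). At day 4 its difference was not detectable (0.03, adjusted p = 0.980). The day 0 call for Smad4 was lost without either WT day 0 library or S4KO day 0 replicate 1. At day 0, against WT, Smad4 also rose in S23DKO (1.34, adjusted p = 0.0019), and Smad2 (1.03, 0.0195) and Smad3 (0.96, 0.0271) in S4KO. A whole-gene count does not test the knockout labels, since a frameshift need not lower the transcript and the edited exons were not given.

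During WT differentiation, genes of the primitive streak and of endoderm came on while naive pluripotency genes were turned down. Eomes, a T-box factor of the early streak, rose from 4.10 ± 0.200 to 245 ± 5.50 CPM (log2 fold change 5.90 ± 0.30, adjusted p = 6.79e-06). T (brachyury) rose from 0.324 ± 0.152 to 113 ± 15.2 CPM (8.45 ± 1.03, adjusted p = 0.000285). The epiblast marker Fgf5 rose from 1.003 ± 0.0730 to 178 ± 15.6 CPM (7.47 ± 1.15, adjusted p = 0.000727). Klf4, a naive pluripotency factor, fell from 181 ± 34.5 to 10.1 ± 3.18 CPM (-4.17 ± 0.68, adjusted p = 0.000966). The largest rises by the naming rule were those of genes with no counts at day 0. Lhx1 was at least 1480-fold higher, Foxa2 at least 1106-fold, Cer1 at least 862-fold, Ttr at least 525-fold, Pcdh7 at least 487-fold and Prss12 at least 477-fold. The largest drops were those of Krt42 (-6.79 ± 0.76), Rarres2 (-6.76 ± 1.21), Calml4 (-6.25 ± 0.56), Mia (-5.21 ± 0.56), Apod (-5.21 ± 0.62) and Khdc3 (-5.20 ± 0.63). Rarres2 fell by 4.26 without WT day 0 replicate 1, and its call was kept there but lost with unfiltered log2(FPKM + 1) (0.0819).

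Of the 18 naive pluripotency genes tested, 17 fell and 0 rose (0 higher and 17 lower adjusted over the list alone; camera adjusted p = 5.00e-10, and adjusted p = 0.298 with an estimated correlation). They included Nr0b1 (-4.64 ± 0.69), Tcl1 (-3.69 ± 0.50) and Klf2 (-3.52 ± 0.71). Of the 14 formative and primed genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 3.17e-05, and adjusted p = 0.414 with an estimated correlation). Sall2 (4.75 ± 0.67), Cdh2 (4.27 ± 0.58) and the DNA methyltransferase gene Dnmt3b (2.60 ± 0.50) were among them. Of the 16 primitive streak genes, 12 rose (13 adjusted over the list alone; camera adjusted p = 1.27e-11, and adjusted p = 0.154 with an estimated correlation). Mixl1 rose by 6.89 ± 0.76 and Fgf8 by 6.20 ± 0.75. Of the 11 definitive endoderm genes 8 rose (8 adjusted over the list alone; camera adjusted p = 5.00e-10). This call held, at adjusted p = 0.0233 with an estimated correlation. Of the 18 extraembryonic endoderm genes 16 rose (16 adjusted over the list alone; camera adjusted p = 2.44e-13, and adjusted p = 0.151 with an estimated correlation). Cubn, the gene of the endocytic receptor cubilin, rose by 9.01 ± 0.71 and Gata4 by 5.02 ± 0.33. The serum-protein gene Afp was 1398-fold higher at day 4 (counting interval 478 to 6779).

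Nodal and activin targets rose on balance with WT differentiation, 7 higher and 1 lower of 14 (8 and 3 adjusted over the list alone; camera adjusted p = 0.000177, and adjusted p = 0.165 with an estimated correlation). Of 14 Wnt targets, 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00112, and adjusted p = 0.298 with an estimated correlation). Axin2 rose by 3.15 ± 0.51. Of the 12 LIF and STAT3 targets 8 fell (10 adjusted over the list alone; camera adjusted p = 0.000168, and adjusted p = 0.298 with an estimated correlation). Socs3 (-3.80 ± 0.42) and Bcl3 (-3.50 ± 0.61) fell in these cells, from which LIF had been withdrawn. Among 25 genes of the TGF-beta superfamily pathway, 12 rose and 4 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.0196, and adjusted p = 0.298 with an estimated correlation). Bmp2 rose (6.43 ± 0.81), as did the receptor gene Bmpr1a (2.00 ± 0.32), while the activin subunit gene Inhbb fell (-4.61 ± 0.93). Imprinted genes rose on balance, 10 higher and 2 lower of 20 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00632, and adjusted p = 0.393 with an estimated correlation). In all, 8157 of 18693 genes differed, 4445 higher and 3712 lower, and the count was 4080 without WT day 0 replicate 1. The WT day 0 libraries carried their own trend with transcript length. Removing each library's length and GC trend moved the share called higher from 54.5% to 40.0%. It kept 70.2% of the calls in the same direction, and 81 called genes were called in the opposite direction.

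In undifferentiated S23DKO cells, the Nodal inhibitor genes Lefty1 and Lefty2 were nearly silent and genes of the trophectoderm and of extraembryonic endoderm were raised. Lefty1, a secreted Nodal inhibitor that is itself a Nodal target, fell from 225 ± 0.941 CPM in WT to 0.0603 ± 0.00234 CPM (log2 fold change -11.81 ± 1.01, adjusted p = 0.000141). Lefty2 fell from 158 ± 9.10 to 0.306 ± 0.258 CPM (-8.98 ± 1.18, adjusted p = 0.00114). Gata3, a trophectoderm transcription factor, rose from 0.408 ± 0.0346 to 14.2 ± 4.83 CPM (5.12 ± 0.52, adjusted p = 0.000364). The placental gene Plac1 rose from 0.0599 ± 0.0847 to 21.02 ± 5.70 CPM (8.46 ± 0.68, adjusted p = 0.000117; 13.04 without WT day 0 replicate 1). Id2, a BMP target, rose from 19.4 ± 1.21 to 107 ± 28.0 CPM (2.46 ± 0.28, adjusted p = 0.000600).

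Other genes that the naming rule picked had no counts in WT at day 0. Serpinb9e was at least 424-fold higher in S23DKO, Pparg at least 290-fold, Csf1r at least 207-fold, Fam90a1b at least 206-fold and Olr1 at least 204-fold. With unfiltered log2(FPKM + 1) values the call for Fam90a1b was lost (0.06, adjusted p = 0.346). Serpinb9 genes are close paralogs, so reads may be assigned to the wrong member. The Y-linked genes Eif2s3y and Uba1y had no counts in S23DKO and were at least 2181-fold and at least 204-fold lower. Ddx3y was 605-fold lower (counting interval 207 to 2939) and Uty 221-fold lower (75.1 to 1073). Of the 4 genes of the Y-linked list 3 fell (3 adjusted over the list alone, camera adjusted p = 0.000285, and adjusted p = 0.317 with an estimated correlation). Xist, whose reads may overlap Tsix because the strand setting was not given, was at 56.6 ± 33.1 CPM in S23DKO and 0.938 ± 0.141 CPM in WT (5.91 ± 0.67, adjusted p = 0.000600).

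By group, 5 of the 14 Nodal and activin targets fell and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.000472, and adjusted p = 0.317 with an estimated correlation). BMP targets went the other way, with 6 of 15 higher and 0 lower (6 adjusted over the list alone; camera adjusted p = 0.00172, and adjusted p = 0.317 with an estimated correlation). Msx2 rose by 3.88 ± 0.35 and Gata2 by 3.94 ± 0.44, while Id1 gave 0.37 and did not pass (adjusted p = 0.529). Of the 14 trophectoderm genes 10 rose (12 adjusted over the list alone; camera adjusted p = 1.03e-06, and adjusted p = 0.188 with an estimated correlation). Of the 18 extraembryonic endoderm genes 9 rose (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000107, and adjusted p = 0.349 with an estimated correlation). They included Gata6 (3.70 ± 0.56) and the basement-membrane collagen genes Col4a1 (3.34 ± 0.42) and Col4a2 (2.98 ± 0.47). Of the 20 imprinted genes 10 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.000107, and adjusted p = 0.317 with an estimated correlation). Plagl1 (4.71 ± 0.48) and Peg10 (3.84 ± 0.35) rose while Grb10 (-1.70 ± 0.31) fell. H19 rose by 7.19 ± 0.48 and Igf2 by 5.13 ± 0.49, a neighbouring pair for which the unknown strand setting leaves some reads uncertain.

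Of the 14 genes of the 2-cell embryo 10 rose (13 adjusted over the list alone; camera adjusted p = 0.000285, and adjusted p = 0.629 with an estimated correlation). The Zscan4 and Usp17l members of this list are repeated families whose reads are hard to place. Pluripotency genes shared by naive and primed cells fell on balance, 4 of 14 lower (4 adjusted over the list alone; camera adjusted p = 0.0221, and adjusted p = 0.629 with an estimated correlation). The call was lost without S23DKO day 0 replicate 2. Pou5f1, which encodes Oct4, gave -1.39 ± 0.33 (adjusted p = 0.00983), and this was lost without WT day 0 replicate 1 (adjusted p = 0.0643) or S23DKO day 0 replicate 2 (0.0669). Within the pathway itself Bmpr1a rose by 1.60 ± 0.32 and Tgfbr1 by 1.45 ± 0.30 while Tgfb1 fell (-2.12 ± 0.43). The pathway list did not pass (7 higher and 2 lower of 25, 10 and 2 adjusted over the list alone; camera adjusted p = 0.188). Genes of mesoderm (5 higher and 3 lower of 18, 5 and 3 adjusted over the list alone; camera adjusted p = 0.660), p53 targets (6 higher and 1 lower of 14, 7 and 2 adjusted over the list alone; 0.187) and Hox genes (3 higher of 11, 3 adjusted over the list alone; 0.0692) did not pass as sets, although Hox genes did with the length and GC correction (4 higher; camera adjusted p = 0.0133). Nor did germ cell genes (4 higher and 2 lower of 13, 4 and 3 adjusted over the list alone; 0.784) or markers of fibroblasts (1 higher of 11, 1 adjusted over the list alone; 0.769). In all, 5799 genes differed, 3114 higher and 2685 lower. The count was 921 without WT day 0 replicate 1, 3105 without WT day 0 replicate 2 and 3021 without S23DKO day 0 replicate 2. With the length and GC correction the share called higher moved from 53.7% to 42.1%.

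In undifferentiated S4KO cells, the BMP targets Id1 and Id2 were lower than in WT, while the BMP list did not pass (camera adjusted p = 0.251). Id1 fell from 50.0 ± 1.73 to 4.65 ± 0.0721 CPM (log2 fold change -3.43 ± 0.46, adjusted p = 0.00516; 0.05003 without WT day 0 replicate 1). Id2 fell from 19.4 ± 1.21 to 6.81 ± 0.268 CPM (-1.51 ± 0.28, adjusted p = 0.00872). The Id2 call was lost without WT day 0 replicate 1 (adjusted p = 0.102) or S4KO day 0 replicate 1 (0.0694). Id3 (-2.15, adjusted p = 0.0446) and Id4 (-1.31, adjusted p = 0.0264) lost their calls without each of the 4 libraries compared, at up to 0.226 and 0.176, as did Id3 with the length and GC correction (0.0881) and Id4 with log2(FPKM + 1) (0.0544). Lefty1 fell to 24.9 ± 8.31 CPM from 225 ± 0.941 CPM in WT (-3.18 ± 0.63, adjusted p = 0.0103). That call was lost without WT day 0 replicate 1 (0.104) or S4KO day 0 replicate 1 (0.0929). Lefty2 gave -2.42 ± 0.84 (adjusted p = 0.0637). Hprt, the purine-salvage gene that E14Tg2a lacks, stood at 208 ± 6.11 CPM in S4KO and 0.541 ± 0.121 CPM in WT (8.57 ± 0.41, adjusted p = 3.73e-06).

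The rule also named Chml (6.63 ± 0.49, adjusted p = 0.000196), Zfp708 (6.44 ± 1.42, adjusted p = 0.0137), Atp7a (5.32 ± 0.65, adjusted p = 0.00345), Tex13b (5.29 ± 0.42, adjusted p = 0.000340) and Pdpr (4.41 ± 0.51, adjusted p = 0.00255) as higher in S4KO. Without WT day 0 replicate 1 the calls for Zfp708 (adjusted p = 0.135), Atp7a (0.0619) and Pdpr (0.0539) were lost. Zfp708 was also lost without WT day 0 replicate 2 (0.0828) or S4KO day 0 replicate 1 (0.0671), and with unfiltered log2(FPKM + 1) (0.0610). Chml had 0.280 ± 0.124 CPM in WT at day 0 and a mean of 22.8 CPM or more in the 5 other groups. Atp7a (0.301 CPM in WT at day 0, 22.6 CPM in WT at day 4) and Pdpr (2.68 and 42.3 CPM) were likewise low in WT at day 0 and not in the other groups. The ubiquitin-ligase gene Mid1, on the X chromosome, fell from 436 ± 75.8 to 0.323 ± 0.105 CPM (-10.39 ± 1.39, adjusted p = 0.00516; 0.0502 without S4KO day 0 replicate 1). Ccl27a (-4.97 ± 0.54), Enpp2 (-4.46 ± 0.55) and Gpa33 (-4.28 ± 0.47) fell as well. Rarres2 (-4.89 ± 1.05, adjusted p = 0.0128) was lost without WT day 0 replicate 1 (log2 fold change -2.39, adjusted p = 0.160) or S4KO day 0 replicate 1 (0.106), and with log2(FPKM + 1) values in limma (0.0658, or 0.166 with no filter). Its alternatives began at 7.33e-06. Pcsk1n (-3.98 ± 1.21, adjusted p = 0.0401) was lost without either WT replicate at day 0 (0.138 without replicate 1, 0.134 without replicate 2) and without S4KO day 0 replicate 1 (0.228) or replicate 2 (0.0552).

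As sets, none of the 26 lists passed in S4KO at day 0. With the length and GC correction, Hox genes (3 higher of 11; camera adjusted p = 0.0352) and 2-cell genes (2 higher of 14; 0.0352) did. BMP targets had 0 higher and 5 lower of 15 (5 adjusted over the list alone; camera adjusted p = 0.251). Nodal and activin targets had 1 higher and 3 lower of 14 (1 and 4 adjusted over the list alone; camera adjusted p = 0.251). Formative and primed genes had 3 lower of 14 (3 adjusted over the list alone; camera adjusted p = 0.0839) and neuroectoderm genes 4 higher of 17 (5 adjusted over the list alone; 0.301). Among 12 mesenchymal genes 3 rose (3 adjusted over the list alone; 0.297). The imprinted gene Mest rose by 3.53 ± 0.34 (adjusted p = 0.00176). In all, 3663 genes differed, 1955 higher and 1708 lower. The length and GC correction called 3606, which included 67.4% of these, and moved the share called higher from 53.4% to 44.9%. The count was 18 without WT day 0 replicate 1, 1286 without WT day 0 replicate 2 and 96 without S4KO day 0 replicate 1.

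At day 4 the S23DKO embryoid bodies had less of most streak and definitive endoderm transcripts than WT and more of trophoblast transcripts. T was at 0.324 ± 0.0607 CPM against 113 ± 15.2 CPM in WT (log2 fold change -8.44 ± 1.02, adjusted p = 0.000500). Eomes was at 6.54 ± 0.870 against 245 ± 5.50 CPM (-5.23 ± 0.29, adjusted p = 1.74e-05). Fgf5 was at 2.79 ± 0.0213 against 178 ± 15.6 CPM (-5.99 ± 1.06, adjusted p = 0.00399). Gata2 rose to 129 ± 12.6 from 1.10 ± 0.588 CPM (6.87 ± 0.51, adjusted p = 4.06e-05). Hand1, a factor of trophoblast giant cells and lateral mesoderm, rose to 67.3 ± 1.47 from 1.27 ± 0.832 CPM (5.73 ± 0.97, adjusted p = 0.00322).

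The rule picked placental genes at the top of the rises, all with no counts in WT. Serpinb9g was at least 600-fold higher, Serpinb9c at least 376-fold, Serpinb9d at least 349-fold, the cathepsin gene Ctsj at least 310-fold, and the prolactin-family genes Prl2c5 at least 201-fold and Prl7d1 at least 182-fold. These are paralog families, so the member is uncertain. DESeq2 did not call Serpinb9c (adjusted p = 0.0993), Ctsj (0.109), Prl2c5 (0.134) or Prl7d1 (0.141), while the other alternatives reached at most 0.00882, 0.0131, 0.0235 and 0.0720. The edgeR call for Prl7d1 was also lost without WT day 4 replicate 1 (adjusted p = 0.0701), WT day 4 replicate 2 (0.0501) or S23DKO day 4 replicate 2 (0.0720). The largest drops were those of Cer1, a Nodal antagonist of the anterior endoderm (1691-fold lower, counting interval 468 to 13973), Mixl1 (-9.76 ± 0.91), T, Trim67 (-8.18 ± 0.95; -13.62 without S23DKO day 4 replicate 1), Lhx1 (-8.03 ± 0.80) and Fgf8 (-7.56 ± 0.80).

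Of the 14 Nodal and activin targets 13 fell and 0 rose (13 adjusted over the list alone; camera adjusted p = 1.14e-25). The call held, at adjusted p = 0.00554 with an estimated correlation. Lefty1 gave -7.03 ± 0.78, Lefty2 -6.27 ± 1.02 and Nodal itself -2.65 ± 0.45. Of the 16 streak genes 14 fell (15 adjusted over the list alone; camera adjusted p = 2.21e-27). Of the 11 definitive endoderm genes 7 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 4.95e-07). Both held with an estimated correlation (adjusted p = 0.0162 and 0.0139). Gsc fell by 5.80 ± 0.81. Of the 14 formative and primed genes 12 fell (13 adjusted over the list alone; camera adjusted p = 1.50e-11, and adjusted p = 0.159 with an estimated correlation). Sox3 (-4.57 ± 0.76), Cdh2 (-3.98 ± 0.57) and Dnmt3b (-2.74 ± 0.50) were among them. Of the 14 trophectoderm genes 13 rose (13 adjusted over the list alone; camera adjusted p = 1.44e-18, and adjusted p = 0.00771 with an estimated correlation, so the call held). Plac1 rose by 7.21 ± 0.58, Gata3 by 5.37 ± 0.51 and the keratin gene Krt19 by 3.73 ± 0.71.

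BMP targets were again raised, 6 higher and 1 lower of 15 (6 and 1 adjusted over the list alone; camera adjusted p = 7.29e-06, and adjusted p = 0.0881 with an estimated correlation). Id2 rose by 2.46 ± 0.28 and Msx2 by 2.14 ± 0.31. Of the 14 Wnt targets 6 fell (9 adjusted over the list alone; camera adjusted p = 4.33e-05, and adjusted p = 0.159 with an estimated correlation). Sp5 fell by 6.07 ± 0.99 and Lef1 by 2.88 ± 0.41. Hypoxia and glycolysis genes were higher on balance, 5 of 15 (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0124, and adjusted p = 0.241 with an estimated correlation). Ndrg1 rose by 2.85 ± 0.30 and Vegfa by 1.94 ± 0.27, while the set was lost without WT day 4 replicate 1 (camera adjusted p = 0.0538). The imprinted genes had 9 higher and 3 lower of 20 (10 and 4 adjusted over the list alone; camera adjusted p = 0.000417, and adjusted p = 0.235 with an estimated correlation). Plagl1 (4.59 ± 0.46), Peg10 (3.92 ± 0.35) and Grb10 (-3.92 ± 0.34) went as at day 0. Of the 14 shared pluripotency genes 4 fell (4 adjusted over the list alone; camera adjusted p = 0.000453, and adjusted p = 0.339 with an estimated correlation). Pou5f1 fell by 2.11 ± 0.33. Extraembryonic endoderm genes, raised at day 0, were lower here, 6 of 18 (7 adjusted over the list alone; camera adjusted p = 0.0110, and adjusted p = 0.397 with an estimated correlation). That call was lost without WT day 4 replicate 2 (0.169).

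Cell cycle genes were lower in S23DKO at day 4, 2 of 16 (2 adjusted over the list alone; camera adjusted p = 0.0177, and adjusted p = 0.397 with an estimated correlation). So were mitochondrial transcripts, 2 of 10 (2 adjusted over the list alone; camera adjusted p = 0.00503, and adjusted p = 0.425 with an estimated correlation), a call lost without WT day 4 replicate 1 (0.142). Naive pluripotency genes were higher on balance, 2 of 18 with 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0274, and adjusted p = 0.626 with an estimated correlation), which was lost without WT day 4 replicate 2 (0.105) or S23DKO day 4 replicate 1 (0.0915). Genes of mesoderm (2 higher and 6 lower of 18, 2 and 6 adjusted over the list alone; camera adjusted p = 0.476), of blood and endothelium (2 higher and 1 lower of 9, 2 and 1 adjusted over the list alone; 0.106) and of mesenchyme (1 higher and 4 lower of 12, 3 and 4 adjusted over the list alone; 0.169) did not pass as sets. Within the pathway list Smad1 (-1.32 ± 0.24) and Foxh1, a partner of Smad2 (-1.41 ± 0.32), fell (0 higher and 2 lower of 25, 2 adjusted over the list alone; 0.476). In all, 2842 genes differed, 1347 higher and 1495 lower. The count was 1558 without WT day 4 replicate 1, 947 without S23DKO day 4 replicate 1, and 868 without S23DKO day 4 replicate 2. It was 4762 with the length and GC correction.

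**Figure D2:**
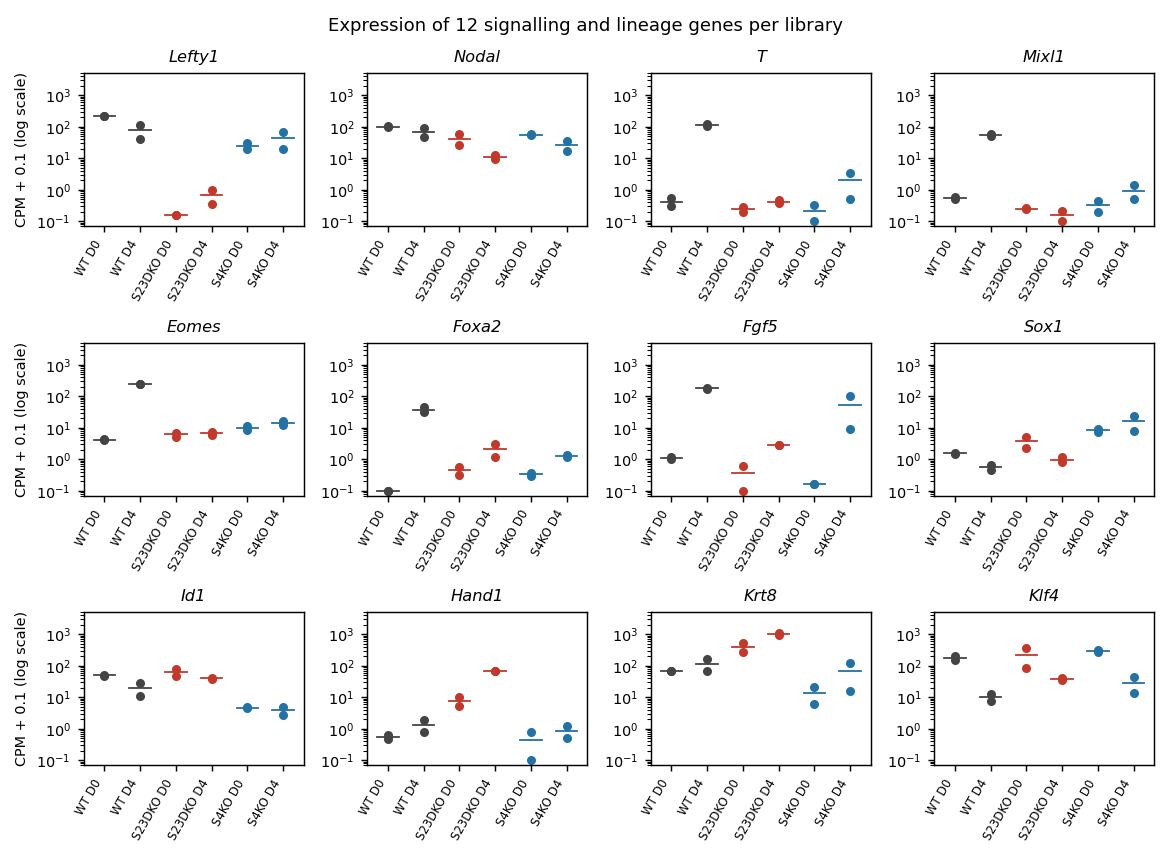
Level of 12 named genes in the 6 groups, as CPM + 0.1 on a log axis; points are libraries and bars are group means. T, Mixl1, Eomes and Foxa2 are high in WT at day 4 and low in both knockouts, Sox1 is highest in S4KO at day 4, and Hand1 and Krt8 are highest in S23DKO at day 4.

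At day 4 the S4KO embryoid bodies also had less of streak and endoderm transcripts than WT, and more of some neuroectoderm transcripts. Eomes was at 14.01 ± 2.53 CPM against 245 ± 5.50 CPM in WT (log2 fold change -4.13 ± 0.27, adjusted p = 5.64e-05). T was at 1.90 ± 2.10 against 113 ± 15.2 CPM (-5.94 ± 0.89, adjusted p = 0.00874). Cubn was at 14.4 ± 0.881 against 334 ± 53.4 CPM (-4.54 ± 0.56, adjusted p = 0.00310). Sox1, a factor of the early neural plate, rose to 16.1 ± 11.7 from 0.458 ± 0.160 CPM (5.12 ± 0.65, adjusted p = 0.00358). Fgf5 (-1.72, adjusted p = 0.408), Lefty1 (-0.80, adjusted p = 0.618) and Krt8 (-0.69, adjusted p = 0.782) did not pass, and their replicates lay far apart.

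The rule further named Hprt (170 ± 1.29 against 0.327 ± 0.111 CPM), Flg (7.31 ± 0.90), Syngr4 (5.82 ± 0.52), Tex13b (4.36 ± 0.40) and Pax6 (3.81 ± 0.55, adjusted p = 0.00663) as higher in S4KO. Pax6 was lost without WT day 4 replicate 1 (adjusted p = 0.0523) or replicate 2 (0.0560). The lower genes were Cer1 (-7.42 ± 0.60), Mixl1 (-6.07 ± 0.73), T, the apolipoprotein gene Apob (-5.75 ± 0.73), Aqp8 (-5.72 ± 0.91, adjusted p = 0.0110) and Prss12 (-5.33 ± 0.77, adjusted p = 0.0166). Aqp8 was lost without S4KO day 4 replicate 1 (adjusted p = 0.0637) and Prss12 without WT day 4 replicate 1 (0.0543) or replicate 2 (0.0514).

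Of the 16 streak genes 13 fell (14 adjusted over the list alone; camera adjusted p = 1.35e-41), and of the 11 definitive endoderm genes 6 (10 adjusted over the list alone; 9.15e-23). So did 10 of the 18 extraembryonic endoderm genes (17 adjusted over the list alone; camera adjusted p = 8.00e-33) and 6 of the 14 Nodal and activin targets (10 adjusted over the list alone; 8.29e-25). All 4 calls held with an estimated correlation (adjusted p = 0.00549, 0.00212, 0.00860 and 0.00489). Foxa2 (-5.04 ± 0.57), Lhx1 (-5.13 ± 0.68), Gata4 (-3.26 ± 0.30) and Dab2 (-3.28 ± 0.49) were among them. In S4KO day 4 replicate 2, Mid1 was at 35.1 CPM against at most 1.13 CPM in the other S4KO libraries, and T at 3.39 CPM against at most 0.415 CPM. Eomes (12.2 and 15.8 CPM) and Cubn (14.4 ± 0.881 CPM) differed little between the replicates. Of the 17 neuroectoderm genes 3 rose and 0 fell (8 adjusted over the list alone; camera adjusted p = 1.05e-07). This too held with an estimated correlation (adjusted p = 0.0179). Naive pluripotency genes were higher as a set, 2 of 18 (15 adjusted over the list alone; camera adjusted p = 7.42e-11, and adjusted p = 0.283 with an estimated correlation). Formative and primed genes were lower, 1 of 14 (6 adjusted over the list alone; camera adjusted p = 2.93e-07, and adjusted p = 0.295 with an estimated correlation).

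Wnt targets were lower in S4KO at day 4, 3 of 14 (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 2.93e-07, and adjusted p = 0.0902 with an estimated correlation). The streak-stage ligand gene Wnt8a fell by 4.42 ± 0.59. LIF and STAT3 targets were higher as a set with no member called (4 higher adjusted over the list alone; camera adjusted p = 0.000126, and adjusted p = 0.283 with an estimated correlation). Genes of the 2-cell embryo were lower with no member called (0 adjusted over the list alone; camera adjusted p = 7.66e-06, and adjusted p = 0.348 with an estimated correlation). BMP targets had 2 lower of 15 (3 adjusted over the list alone; camera adjusted p = 0.0125, and adjusted p = 0.303 with an estimated correlation). That call was lost without WT day 4 replicate 2 or S4KO day 4 replicate 1. Hypoxia and glycolysis genes were higher as a set, 1 of 15 (1 adjusted over the list alone; camera adjusted p = 0.0412, and adjusted p = 0.312 with an estimated correlation), a call lost without WT day 4 replicate 1 (0.200) or S4KO day 4 replicate 1 (0.0871). Mitochondrial transcripts were lower with no member called (0 adjusted over the list alone; camera adjusted p = 0.000395, and adjusted p = 0.358 with an estimated correlation), a call lost without WT day 4 replicate 1 (0.200) or S4KO day 4 replicate 2 (0.0529). The imprinted genes Plagl1 (3.58 ± 0.44) and Mest (3.02 ± 0.34) rose, while their list did not pass (2 higher of 20, 2 adjusted over the list alone; camera adjusted p = 0.454). In all, 323 genes differed, 127 higher and 196 lower. Chromosome 8, which holds 5.19% of the tested genes, held 14.6% of them. The count was 115 without WT day 4 replicate 1, 174 without WT day 4 replicate 2, 78 without S4KO day 4 replicate 1 and 578 without S4KO day 4 replicate 2. DESeq2 called 1049 genes. The length and GC correction gave 982 and moved the share called higher from 39.3% to 57.3%.

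**Figure D3:**
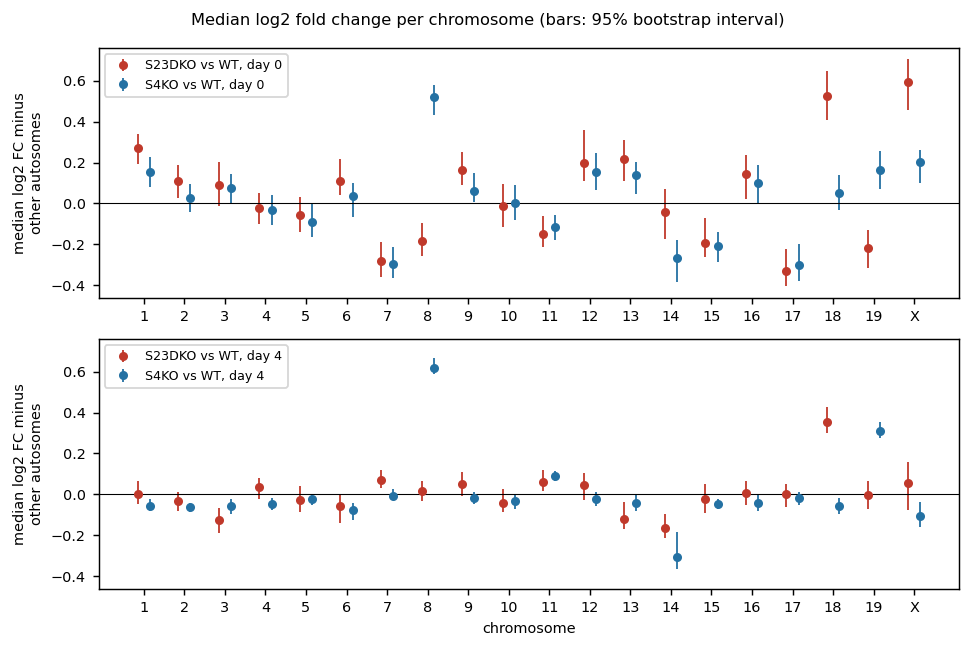
Median log2 fold change against WT of the genes on each chromosome, minus that of the other autosomes, for S23DKO and S4KO, with 95% bootstrap intervals; day 0 is the upper panel and day 4 the lower. Chromosome 8 is raised in S4KO at both days (0.521 and 0.620), and the X chromosome is raised in S23DKO at day 0 (0.594), not at day 4 (0.0538).

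Within S23DKO, differentiation lowered naive pluripotency genes and raised trophectoderm and extraembryonic endoderm genes, but streak genes were not raised as a set. Nanog fell from 686 ± 60.2 to 150 ± 18.97 CPM (log2 fold change -2.19 ± 0.25, adjusted p = 0.00273; 0.0552 without S23DKO day 4 replicate 2), and T gave 1.19 (adjusted p = 0.540). Of the 18 naive genes 11 fell (15 adjusted over the list alone; camera adjusted p = 3.11e-12, and adjusted p = 0.254 with an estimated correlation). Of the 14 trophectoderm genes 4 rose (9 adjusted over the list alone; camera adjusted p = 8.68e-08, and adjusted p = 0.198 with an estimated correlation). So did 8 of the 18 extraembryonic endoderm genes (13 adjusted over the list alone; camera adjusted p = 7.92e-08, and adjusted p = 0.226 with an estimated correlation). The streak list had 1 higher and 1 lower of 16 (1 and 1 adjusted over the list alone; camera adjusted p = 0.947). Zfp469 (4.68 ± 0.57) and Mogat2 (4.48 ± 0.60) rose, and the neuronal gene Stmn2 (-3.99 ± 0.23) and Pianp (-3.77 ± 0.42) fell.

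The rule also named Ttr, Aqp8, Fgf17 and Zmat4 in S23DKO. Ttr was at least 182-fold higher at day 4. This call was lost when any S23DKO library was left out, and in DESeq2 (adjusted p = 0.0745). The other calls were lost without S23DKO day 0 replicate 1, day 4 replicate 1 or day 4 replicate 2. In that order, Aqp8 (4.53 ± 0.85) was at adjusted p = 0.0655, 0.0681 and 0.0817, Fgf17 (-4.52 ± 0.86) at 0.0601, 0.0938 and 0.142, and Zmat4 (-3.84 ± 0.92) at 0.2999, 0.157 and 0.224. Without S23DKO day 0 replicate 1 the log2 fold change was -2.18 for Fgf17 and -1.21 for Zmat4. With log2(FPKM + 1) Fgf17 was at 0.0567 and Zmat4 at 0.161, and unfiltered at 0.122 and 0.278. Zmat4 was also lost with log2(FPKM + 0.1) (0.0826) and with only these groups (0.0964). In all, 1315 genes differed, 668 higher and 647 lower. The count was 283 without S23DKO day 0 replicate 1, 69 without S23DKO day 4 replicate 1, and 38 without S23DKO day 4 replicate 2. It was 2695 with DESeq2 and 3175 with the length and GC correction, which moved the share called higher from 50.8% to 38.0%. Without the WT day 0 libraries, 785 genes were called.

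Within S4KO, differentiation raised formative and primed genes and lowered naive genes. Fgf5 rose from 0.0608 ± 0.00188 to 53.9 ± 63.7 CPM (log2 fold change 9.73 ± 1.40, adjusted p = 0.00408). Fgf5 was at 98.9 CPM in replicate 2 of day 4, the library with Mid1 transcripts, and without it rose by 7.12 (adjusted p = 0.00619). Dnmt3b (2.23) and Pou3f1 (3.93) rose too. These calls were lost without S4KO day 4 replicate 2 (log2 fold change 1.14, adjusted p = 0.230 for Dnmt3b; 2.16 and 0.0880 for Pou3f1) or S4KO day 0 replicate 2 (0.114 and 0.0670), and with unfiltered log2(FPKM + 1) values in limma (0.0529 and 0.0720). Otx2, a regulator of the exit from the naive state, rose from 11.1 ± 4.02 to 87.6 ± 46.3 CPM (2.98 ± 0.42, adjusted p = 0.00393). Of the 14 formative and primed genes 10 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 5.78e-09, and adjusted p = 0.351 with an estimated correlation). Of the 18 naive genes 6 fell (1 higher and 13 lower adjusted over the list alone; camera adjusted p = 2.42e-09, and adjusted p = 0.351 with an estimated correlation). Eomes gave 0.52 (adjusted p = 0.210). The streak list had 6 higher of 16 (6 adjusted over the list alone; camera adjusted p = 0.0121, and adjusted p = 0.486 with an estimated correlation). That was lost without S4KO day 0 replicate 1 (0.0700). The rule named Fndc3c1 (6.15 ± 0.78), Sema6a (6.13 ± 0.80; 4.04 without S4KO day 4 replicate 2) and Car4 (6.10 ± 0.81) as higher. Emp1 (-4.83 ± 0.33), Xaf1 (-4.53 ± 0.38), Catip (-4.25 ± 0.44) and Fcgr2b (-4.21 ± 0.92, adjusted p = 0.0179) were lower. Fcgr2b gave adjusted p = 0.0568 without S4KO day 4 replicate 2, and a log2 fold change of -11.03 without S4KO day 4 replicate 1. In all, 1663 genes differed, 950 higher and 713 lower. The count was 998 without S4KO day 0 replicate 1, 712 without S4KO day 0 replicate 2, and 225 without S4KO day 4 replicate 2. It was 2895 with DESeq2, 16 with only these 2 groups in the fit, and 3358 with the length and GC correction, which moved the share called higher from 57.1% to 40.0%. The fit with only these 2 groups also ended the calls for Fgf5, Otx2, Dnmt3b, Pou3f1, Fndc3c1, Sema6a, Car4, Catip and Fcgr2b, at adjusted p from 0.0668 for Catip to 0.0971 for Dnmt3b.

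At day 0, S4KO had less of the BMP targets and trophectoderm genes than S23DKO, and more Lefty1. Lefty1 was higher in S4KO (log2 fold change 8.63 ± 0.95, adjusted p = 0.000773). Id1 (-3.79 ± 0.47, adjusted p = 0.00147), Id2 (-3.97 ± 0.30, adjusted p = 0.000111) and Msx2 (-3.75 ± 0.35) were lower. Of the 14 trophectoderm genes 8 were lower (13 adjusted over the list alone; camera adjusted p = 2.52e-19) and of the 15 BMP targets 7 (8 adjusted over the list alone; camera adjusted p = 1.87e-11). Both calls held with an estimated correlation (adjusted p = 0.0118 and 0.0397). Of the Nodal and activin targets 3 of 14 were higher (3 adjusted over the list alone; camera adjusted p = 0.000994, and adjusted p = 0.201 with an estimated correlation). Plac1 (-7.81 ± 0.64), Gata3 (-4.99 ± 0.52) and the imprinted gene Peg10 (-4.65 ± 0.36) were lower as well. The rule named Eif2s3y (at least 1262-fold higher in S4KO), Uba1y (at least 396-fold) and Ddx3y (1117-fold, counting interval 382 to 5421) beside Lefty1. Pcdh12 (at least 233-fold), Csf1r (at least 232-fold), Olr1 (at least 228-fold) and Mid1 (-9.58 ± 1.36) were lower in S4KO. In all, 1034 genes differed, 402 higher and 632 lower in S4KO. The count was 1607 without S23DKO day 0 replicate 1, 334 without S23DKO day 0 replicate 2, 412 without S4KO day 0 replicate 1 and 632 without S4KO day 0 replicate 2. It was 2112 with DESeq2, 1592 with no filter, 393 with only these 2 groups in the fit, and 2484 with the length and GC correction, which moved the share called higher from 38.9% to 55.2%.

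At day 4 the same contrast parted trophoblast from neural transcripts. S4KO had more Sox1 (log2 fold change 4.19 ± 0.61, adjusted p = 0.00189) and Pax6 (3.73 ± 0.55, adjusted p = 0.00189) than S23DKO, and less Hand1 (-6.49 ± 1.02, adjusted p = 0.00276), Gata2 (-5.77 ± 0.48) and Plac1 (-7.93 ± 0.61). Of the 14 trophectoderm genes 13 were lower (13 adjusted over the list alone; camera adjusted p = 5.36e-19), and of the 15 BMP targets 6 (9 adjusted over the list alone; camera adjusted p = 2.43e-11). Id1 (-3.41 ± 0.46) and Id2 (-2.76 ± 0.28) were among them, and both sets held with an estimated correlation (adjusted p = 0.0169 and 0.0435). Of the Nodal and activin targets 7 of 14 were higher (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.60e-06, and adjusted p = 0.0661 with an estimated correlation). Of the 17 neuroectoderm genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.00184, and adjusted p = 0.116 with an estimated correlation). Extraembryonic endoderm genes were lower, 9 of 18 (12 adjusted over the list alone; camera adjusted p = 3.14e-09, and adjusted p = 0.116 with an estimated correlation), Gata4 (-2.21 ± 0.29) and Lama1 (-2.45 ± 0.24) among them. The rule named Hprt (9.18 ± 0.42), Lefty1 (6.23 ± 0.76), Kcnj3 (6.06 ± 0.79) and Eif2s3y (5.92, adjusted p = 0.00479; 13.98 without S23DKO day 4 replicate 1) as higher. Olr1 (at least 575-fold), Serpinb9g (at least 480-fold), Csf1r (at least 411-fold) and Serpinb9c (at least 301-fold; adjusted p = 0.124 in DESeq2) were lower. In all, 2298 genes differed, 1092 higher and 1206 lower in S4KO. The count was 747 without S23DKO day 4 replicate 1, 632 without S23DKO day 4 replicate 2, 1349 without S4KO day 4 replicate 1, and 1050 without S4KO day 4 replicate 2. It was 4386 with the length and GC correction and 4508 with only these 2 groups in the fit.

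The genotype effects changed between the days at several streak and endoderm genes, among others. For Eomes the S23DKO effect was lower at day 4 than at day 0 (-5.79 ± 0.37, adjusted p = 9.02e-05), as it was for Cubn (-6.47 ± 0.79, adjusted p = 0.00664). For Gata4 the S4KO effect was lower at day 4 (-4.92 ± 0.42, adjusted p = 0.000430), as it was for Cemip, which encodes a hyaluronan-binding protein (-7.84 ± 0.67, adjusted p = 0.000430). Fgf5 (-4.10, adjusted p = 0.107) in S23DKO and T (-4.55, adjusted p = 0.138), Mixl1 (-5.06, adjusted p = 0.0712) and Sox1 (2.66, adjusted p = 0.121) in S4KO did not pass this test, so their genotype effects were not shown to differ between the days. Of the 16 streak genes the effect was lower at day 4 for 10 in S23DKO (11 adjusted over the list alone; camera adjusted p = 3.47e-17, and adjusted p = 0.0774 with an estimated correlation). In S4KO it was lower for 2 of them (11 adjusted over the list alone; camera adjusted p = 3.10e-14, and adjusted p = 0.0831 with an estimated correlation). Of the 11 definitive endoderm genes it was lower for 3 in S4KO (1 higher and 6 lower adjusted over the list alone; camera adjusted p = 5.10e-10, and adjusted p = 0.0195 with an estimated correlation, so the call held).

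In all, the S23DKO effect differed between days for 1140 genes, 343 higher and 797 lower at day 4. The S4KO effect differed for 28 genes, 2 higher and 26 lower. The S23DKO count was 28 without WT day 0 replicate 1, 137 without WT day 0 replicate 2, 86 without WT day 4 replicate 1, and 3887 without WT day 4 replicate 2. It was 453 without S23DKO day 0 replicate 1, 725 without S23DKO day 0 replicate 2, 38 without S23DKO day 4 replicate 1 and 32 without S23DKO day 4 replicate 2. The S4KO count was 14 without WT day 0 replicate 1, 16 without WT day 4 replicate 1, 2008 without WT day 4 replicate 2, 712 without S4KO day 0 replicate 2 and 81 without S4KO day 4 replicate 2. With the length and GC correction the share called higher moved from 30.1% to 53.6% in S23DKO and from 7.14% to 55.0% in S4KO.

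Both knockouts were set against the same WT libraries, so calls common to both are expected from the controls alone, and the number to expect was not simulated. At day 0, 1356 genes were higher in both and 1221 lower in both, while 15 were higher in S23DKO and lower in S4KO and 7 the reverse. At day 4, 62 genes were higher in both and 101 lower in both. Eomes, Mixl1, T, Cer1 and Lhx1 were among the latter. Across genes, the 2 sets of log2 fold changes had a Pearson r of 0.607 and a Spearman rho of 0.673 at day 0, and 0.423 and 0.401 at day 4. Genes are not independent replicates. The shared WT libraries alone gave a mean r of 0.503 at day 0 and 0.494 at day 4, and a mean rho of 0.476 and 0.466, in 20 simulations without any genotype effect. On their scale and genes the real r was 0.647 and 0.434, and rho 0.685 and 0.398, at day 4 below the simulated means. Effects in 1 knockout alone can lower r, so this does not assign the overlap to the controls. The covariance exceeded its simulated mean at both days, 0.729 against 0.118 and 0.407 against 0.123. With a different WT replicate per knockout, r was 0.425 or 0.420 at day 0 and 0.226 or 0.242 at day 4. Of the 114 list calls in the 11 contrasts, 15 held with an estimated correlation, each named as such above, and no called list had a median, mean and test of different sign. The other calls that stayed when any 1 library was left out passed at the preset correlation only; beside their members called stand those adjusted over the list alone. From day 0 to day 4 in S23DKO they were mitochondrial transcripts (4 of 10 lower, 9), cell cycle genes (3 of 16 lower, 10), LIF targets (3 of 12 lower, 8), hypoxia genes (5 of 15 higher, 9), definitive endoderm (4 of 11 higher, 6 and 1 lower) and imprinted genes (5 higher and 1 lower of 20, 7 and 1). In S4KO they were mitochondrial transcripts (1 of 10 lower, 4), LIF targets (3 of 12 lower, 7), Wnt targets (5 of 14 higher, 5), extraembryonic endoderm (6 higher and 1 lower of 18, 9 and 1) and imprinted genes (7 of 20 higher, 8). In S4KO against S23DKO they were, at day 0, extraembryonic endoderm (5 of 18 lower, 7), Y-linked (4 of 4 higher, 4) and imprinted genes (2 higher and 7 lower of 20, 2 and 9), and at day 4 streak (4 of 16 higher, 8) and 2-cell genes (3 of 14 lower, 5). Calls for Y-linked genes in S23DKO against WT and in S4KO against S23DKO, and for shared pluripotency in the latter, also stayed at day 4. Other list calls not described ended when 1 library was left out.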

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

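The tests of an extra copy of chromosome 8, of the comparison of X-linked genes with S4KO and of Mid1 against the other S4KO libraries were chosen after the result was seen, and so was the length and GC correction.

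These results were picked out because the difference between a knockout and WT itself changed from day 0 to day 4. The S23DKO effect did so for 1140 genes and the S4KO effect for 28, counts that ran from 28 to 3887 and from 14 to 2008 when single libraries were left out. The lowest counts came without WT day 0 replicate 1 and the highest without WT day 4 replicate 2.

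In S23DKO the effect on Rarres2, which encodes chemerin, was higher at day 4 by 9.30 (SE 1.52, log2), on Dnajc5g by 4.93, on Lefty1 by 4.78 and on Calml4 by 4.72. Without WT day 0 replicate 1 these calls ended, at adjusted p = 0.0568 for Rarres2, 0.117 for Dnajc5g, 0.153 for Lefty1 and 0.0568 for Calml4. Rarres2 was also lost without WT day 4 replicate 1 (0.0721) or S23DKO day 4 replicate 1 (0.0529). Dnajc5g was lost without WT day 0 replicate 2, WT day 4 replicate 1 or any S23DKO library. It stood at 8.50 without WT day 4 replicate 2. With log2(FPKM + 1) Dnajc5g gave 0.686 with and 0.758 without a filter, and with log2(FPKM + 0.1) 0.0671, while Rarres2 gave 0.0632 with log2(FPKM + 1) unfiltered. Lefty1 was lost without WT day 0 replicate 2 (0.0836), WT day 4 replicate 1 (0.116), S23DKO day 0 replicate 1 (0.0948) or replicate 2 (0.0951), or S23DKO day 4 replicate 1 (0.179) or replicate 2 (0.0821), and also with the replicate block, the length and GC correction (0.0542 each) and log2(FPKM + 1) with (0.0953) and without (0.192) a filter. Over all alternatives the adjusted p ran from 7.86e-09 to 0.0721 for Rarres2, from 0.000386 to 0.758 for Dnajc5g, from 0.000170 to 0.192 for Lefty1 and from 9.65e-10 to 0.0568 for Calml4.

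Streak and endoderm genes went the other way. The fitted differences for Lhx1 (-13.86), Foxa2 (-11.29), Evx1 (-11.05) and Nostrin (-10.53) in S23DKO depend on the prior count, since groups without counts enter them, and are no bounds. T gave -7.27, Mixl1 -8.19, Eomes -5.79, Gata6 -4.51 and Cubn -6.47. Eomes, Cubn, Lhx1 and Foxa2 kept their calls in every fit that left out a library. Mixl1 was lost without WT day 0 replicate 1 (adjusted p = 0.0721) and stood at -12.81 without S23DKO day 4 replicate 1. Evx1 was lost without WT day 0 replicate 1 (0.101) or replicate 2 (0.0570), S23DKO day 0 replicate 1 (0.0694), or S23DKO day 4 replicate 1 (0.0541) or replicate 2 (0.0773). Nostrin was lost without WT day 0 replicate 1 (0.0976) or replicate 2 (0.0548), WT day 4 replicate 1 (0.0536), or S23DKO day 4 replicate 1 (0.0567) or replicate 2 (0.0767). Gata6 was lost without WT day 0 replicate 1 (0.0975) or replicate 2 (0.0570), or S23DKO day 4 replicate 1 (0.0539) or replicate 2 (0.0786). T was lost without either WT day 0 library, WT day 4 replicate 1 or any S23DKO library.

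In S4KO the effect on Plekha4 was higher at day 4 (3.49), and lower on Foxa2 (-11.58, again dependent on the prior count and no bound), Cemip (-7.84), Apob (-6.96), Chml (-6.37), Cubn (-5.46), Gata6 (-5.54) and Gata4 (-4.92). Foxa2, Cemip, Chml and Gata4 kept their calls in every fit that left out a library. Without WT day 0 replicate 1 the adjusted p was 0.194 for Plekha4, Apob and Cubn and 0.129 for Gata6. Without WT day 0 replicate 2 it was 0.0671 for Plekha4, Cubn and Gata6 and 0.0702 for Apob. Without WT day 4 replicate 1 it was 0.0797 for Plekha4 and Apob and 0.0885 for Cubn. Without S4KO day 0 replicate 1 it was 0.0991 for Plekha4, 0.0657 for Apob and 0.0840 for Cubn. Without S4KO day 4 replicate 1 it was 0.0756 for Plekha4 and 0.0819 for Cubn. Plekha4 was also lost with the replicate block (0.0527) and with only the groups compared (0.0851), and Chml with log2(FPKM + 1) unfiltered (0.0825).

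As sets, the S23DKO effect differed between days for Nodal and activin targets (camera adjusted p = 3.20e-05), naive genes (0.0190), formative and primed genes (1.38e-05), streak genes (3.47e-17), definitive endoderm (2.91e-06), extraembryonic endoderm (9.12e-10), 2-cell genes (0.00106), Wnt targets (0.00507) and mitochondrial transcripts (0.000138). In that order these sets gave adjusted p = 0.120, 0.750, 0.424, 0.0774, 0.0504, 0.132, 0.600, 0.424 and 0.424 with an estimated correlation. The naive set was lost without WT day 4 replicate 2 or S23DKO day 0 replicate 2, and the Wnt set without WT day 4 replicate 2 or S23DKO day 0 replicate 1. The S4KO effect differed for Nodal and activin targets (0.000118), naive genes (0.000841), streak genes (3.10e-14), definitive endoderm (5.10e-10), extraembryonic endoderm (4.73e-19), 2-cell genes (1.11e-07) and mitochondrial transcripts (0.00119). Definitive endoderm held (adjusted p = 0.0195 with an estimated correlation), and the others in order gave 0.141, 0.643, 0.0831, 0.0616, 0.545 and 0.577. The naive set was lost without S4KO day 4 replicate 1.

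In S23DKO, where Xist was raised, Eif2s3y and Uba1y stood at 0% of WT day 0, Ddx3y at 0.160% and Uty at 0.463%, while the Y-linked gene model Gm47283 stood at 31.1%, just under the bound set beforehand against loss of the Y. X-linked genes lay above autosomal genes by 0.594 against WT at day 0 (interval 0.455 to 0.705) and by 0.340 against S4KO (0.231 to 0.489), but at day 4 the difference from WT was 0.0538 (-0.0768 to 0.159), and S4KO lay at -0.187 against S23DKO (-0.309 to -0.0610). A length and GC trend is not the whole cause, since the X difference was 0.393 after the correction (0.286 to 0.502). An XX line with both X chromosomes active and the loss of the Y chromosome from an XY line cannot be told apart without genomic DNA or the history of the clones, and an effect of the Smad genes on Xist was not tested. The bound set beforehand against loss of the Y was passed with WT as reference, but it was set aside because WT itself differed on the X by 0.39 between days without a change of genotype, and the value against S4KO lies between the bounds of the 2 explanations.

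Genes on chromosome 8 were raised in S4KO, by 0.521 (0.435 to 0.577) at day 0 and 0.620 (0.589 to 0.665) at day 4 against WT, and by 0.658 and 0.620 against S23DKO, near the 0.585 that 3 copies in place of 2 in all cells would give. A length and GC trend is not the cause, since the day 0 value was 0.573 (0.524 to 0.626) after the correction. Of 4 parts of the chromosome with equal numbers of genes, the lowest gave 0.231 (0.109 to 0.387) against WT at day 0, and the same part 0.363 (0.262 to 0.480) after the correction, 0.502 against WT at day 4 and 0.578 against S23DKO at both days. The intervals at day 0 against WT include the bound of 0.3, set after the result was seen, and the other values lie above it, so an extra copy is not excluded, and a change of expression along the chromosome was not told apart from it. Of the 323 genes called in S4KO at day 4, 43 were raised and 4 lowered on this chromosome, and some of the 43 may reflect the clone and not the loss of Smad4.

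S4KO day 4 replicate 2 held transcripts of 14 genes of WT day 4, each picked as being at most 2% of the WT level in the other S4KO libraries, which leaves out genes such as Eomes (12.2 and 15.8 CPM) and Cubn that were alike in both replicates. Mid1 was 31.0 times its highest level in the other S4KO libraries. It rose from at most 0.396 CPM (day 0) to 1.13 CPM in day 4 replicate 1. Differentiation of the S4KO cells was thus not excluded. WT day 4 cells or reads in this library are another candidate. The median share of the WT day 4 level over these genes was 4.60% (3.42 to 5.74), beside 6.09% for Mid1. Single genes ran from 0.741% for Cer1 to 16.2% for Pcdh7, so the share is not uniform.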

How the results depend on the processing

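Tests with the length and GC correction, without the WT day 0 libraries, with single libraries left out for the lists and without chromosomes 8, X and Y were chosen only after the result was seen. The 11 counts of called genes stayed within 1.5 times their value under a minimum absolute log2 fold change of 1, the replicate block and the omission of chromosomes 8, X and Y. Smad3 in S23DKO at day 0 (0.63) came past the threshold with DESeq2 (0.65), with a minimum of 1 CPM (0.68) and with limma on log2(FPKM + 0.1) (0.82). Smad2 at day 4 (-0.80) did so with DESeq2 (-0.77), no filter (-0.83) and the length and GC correction (-0.58), and Smad3 at day 4 (-0.70) with that correction (-0.86). Smad4 in S4KO at day 0 (0.82) no longer passed when a log2 fold change of 1 was required, as that setting by its construction excludes smaller changes. DESeq2 called 1049 genes for S4KO against WT at day 4 (323 in edgeR), 2695 and 2895 for day 4 against day 0 in S23DKO and S4KO (1315 and 1663), 2112 for S4KO against S23DKO at day 0 (1034), and 3227 and 1533 for the change of the S23DKO and S4KO effects between days (1140 and 28). With no filter the counts were 754 for S4KO at day 4, 1592 for S4KO against S23DKO at day 0, and 2549 and 862 for the changes of effect. The change of the S4KO effect gave 47 genes with RLE, 61 with a minimum of 1 CPM, 211 with log2(FPKM + 1), 102 with log2(FPKM + 0.1) and 220 with log2(FPKM + 1) unfiltered. The last of these gave 598 for S4KO at day 4, and log2(FPKM + 1) gave 1876 for the change of the S23DKO effect. Fits with only the groups compared gave 128 for S4KO at day 4, 16 for S4KO day 4 against day 0, and 393 and 4508 for S4KO against S23DKO at day 0 and day 4. Without the WT day 0 libraries, 175 genes were called for S4KO at day 4 and 785 for S23DKO day 4 against day 0. The length and GC correction gave 4762 and 982 for S23DKO and S4KO at day 4, 3175 and 3358 for day 4 against day 0 in these genotypes, 2484 and 4386 for S4KO against S23DKO at day 0 and day 4, and 298 for the change of the S4KO effect. For the shared effect at day 0, Pearson r, Spearman rho and covariance were 0.704, 0.776 and 0.674 for genes of at least 5 CPM, 0.571, 0.600 and 1.17 with the correction, 0.425, 0.589 and 1.179 with WT replicate 1 as control for S23DKO and replicate 2 for S4KO, and 0.420, 0.582 and 1.185 with the WT replicates exchanged. At day 4 these WT splits gave 0.226, 0.120 and 0.545, and 0.242, 0.180 and 0.586, genes of at least 5 CPM gave r 0.441 and covariance 0.243, and the correction gave rho 0.389. Except where construction is named, the cause was not tested. Leaving out 1 library, the counts ran from 921 to 5073 for S23DKO and 18 to 3598 for S4KO against WT at day 0, 868 to 3040 and 78 to 578 at day 4, 4080 to 8042, 38 to 1208 and 225 to 1815 for day 4 against day 0 in WT, S23DKO and S4KO, 334 to 1607 and 632 to 1349 for S4KO against S23DKO at day 0 and day 4, and 28 to 3887 and 14 to 2008 for the changes of the S23DKO and S4KO effects. Smad3 at day 0 ran from 0.32 to 0.92, Smad2 at day 4 from -1.08 to -0.47 and Smad4 at day 0 from 0.64 to 1.00018. Of 1604 fits of a named gene with 1 library left out, 1238 kept the call or its absence, 350 lost it and 16 gained it. Of 520 such list tests, 468 kept the call, 51 lost it and 1 reversed. That was the naive set in S4KO against S23DKO at day 4, at camera adjusted p = 0.691 without S4KO day 4 replicate 1, in a range from 1.16e-07 to 0.691. Among 372 named gene results, the call changed for 22 with DESeq2, 2 with RLE, 17 with no filter, 42 with only the groups compared, 65 with log2(FPKM + 1) unfiltered and 15 with the correction. For 362 of them with a filtered FPKM value it changed for 32 with log2(FPKM + 1) and 24 with log2(FPKM + 0.1). Of 114 list calls, 70 passed with fry, which asks a different question, and 44 did not. The correction ended the list calls for Hox genes (0.123) and blood and endothelium (0.101) in S4KO at day 4, germ cell genes in S23DKO day 4 against day 0 (0.180), shared pluripotency (0.0654), neuroectoderm (0.0536) and germ cell genes (0.107) in S4KO day 4 against day 0, 2-cell genes in S4KO against S23DKO at day 0 (0.0525) and naive genes at day 4 (0.0611). It brought below 0.05 definitive endoderm (0.00956) and Hox genes (0.0133) in S23DKO at day 0, 2-cell and Hox genes in S4KO at day 0 (0.0352 each), p53 targets in S23DKO at day 4 (0.0392), mesoderm (0.00281), 2-cell and cell cycle genes (0.0226 each) in WT, the pathway (0.0188), mesoderm (0.00212) and mesenchyme (0.0183) for the change of the S23DKO effect, and mesoderm (0.0431) and Wnt targets (0.00403) for that of the S4KO effect. The labels give no batch, but the sample numbers in the descriptions were consecutive for day 0 and day 4 of the same replicate in both knockouts and 1 number occurs in 2 libraries, which leaves more than 1 sequencing run open. The correlations of replicate deviations were 0.0671 between the days of S23DKO, -0.0239 between those of S4KO, and -0.147 to 0.339 over all 15 pairs of groups. With the replicate number as a block, 12 of the 372 named gene results changed, and 1 of 114 list calls was lost (mesoderm in S4KO day 4 against day 0, 0.0520). The sample numbers themselves were not modelled. The median log2 fold change of all genes moved with log2(FPKM + 1) to 0.13 and 0.11 for S23DKO and S4KO at day 0 (0.02 and 0.01), with log2(FPKM + 0.1) to 0.17 and 0.15, to 0.08 for S23DKO at day 4 (-0.03), to 0.20 for WT day 4 against day 0 (0.08) and to -0.15 for the change of the S4KO effect (-0.04). With the correction it moved to -0.09 for S23DKO at day 0, to -0.12 for WT and to 0.08 for both changes of effect. RLE moved the share higher among the changes of the S4KO effect from 7.14% to 19.1%. Where a group had no counts for a gene, depth limits the fold to its bound from the floor of 3 counts.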

Other observations

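All values here were chosen after they were seen. Among genes at 5 CPM or more with a 4-fold separation from the other genotypes at both days, 27 were higher and 5 lower in S23DKO, 3 higher and 1 lower in S4KO, and 0 either way in WT. Of the 27, 15 are X-linked, as are 2 of the 3.

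Hprt, which E14Tg2a lacks, was at most at 0.724 CPM outside S4KO. Tex13b stood at 22.96 ± 1.91 and 18.3 ± 2.65 CPM in S4KO at the 2 days.

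Chml (0.280 CPM), Atp7a (0.301), Nr2c2 (1.90) and Pdpr (2.68) were low in WT day 0 and had means of at least 12.3 CPM in each of the 5 other groups.

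In S23DKO day 4 replicate 1 the Y-linked genes Eif2s3y, Ddx3y and Uty had 84, 66 and 27 counts, against 0 to 3 in the other S23DKO libraries.

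Xist stood at 4.30 ± 3.67 CPM in S4KO day 0, 8.58 ± 1.51 CPM in WT day 4, 98.4 ± 23.4 CPM in S23DKO day 4 and 6.84 ± 1.22 CPM in S4KO day 4.

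In WT day 0, gene level against exon length gave a Spearman rho across genes of -0.405 and -0.356 after centring on the mean of all libraries, and between -0.187 and 0.260 in the other libraries.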
